A study of Homo sapiens with 12 samples.

How the data were processed

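The data were peak lists of m6A-enriched RNA from 143B cells, 1 list for each of 6 immunoprecipitated libraries. There were 3 libraries of ALKBH5 knockdown and 3 of scrambled siRNA, taken at 48 h. The 6 input samples were not analysed here. Samples were put in groups by their titles and treatment labels. For the control input of replicate 3 the labels name the sample type of an immunoprecipitate while its title and antibody field name an input, and it entered no comparison.

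Per the submitters' processing notes, the reads were handled with CASAVA 1.8.2, TopHat2 and SAMtools on the hg19 genome. The roles of these tools, the peak caller, its threshold and whether input reads entered the calling are not given in the sources used here. Each deposited list held 12 columns, with a position, a strand, exon blocks, a gene number and a score per peak. The lists were separate for each library, so peaks were called per library and not on pooled samples. The score that the authors deposited for each peak was taken as a p-value from its range, 0 to 0.011 over all lists, since the file headers name it only as a score. It fell with peak length (Spearman correlation across peaks, from -0.79 to -0.87 per list). The score was used only to rank or filter peaks within a list, never to compare lists. A stricter threshold shortens a list and more reads can lengthen it, so differences between libraries in list size cannot be separated from depth, which is unknown because the lists hold no counts. No interval for depth could be given.

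Peak length was the summed length of exon blocks. Peaks of all 6 lists were joined into regions where their blocks overlapped by at least 1 bp on the same strand, and a library called a region if it had a peak in it. A gene was called in a library with at least 1 peak that carried its number, and peaks without a gene number, 7.4 to 8.6% of each list, entered the regions but not the genes. Between 7 and 43 positions per list were listed for more than 1 gene. Gene numbers were turned into symbols through a RefSeq gene table of the GRCh38.p14 assembly, used for names only: 10500 of 10536 numbers matched and 36 did not. Printed coordinates are those of the lists (hg19), counted from 1.

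Before the data were examined, the tests, the alternatives, 20 gene lists with 450 entries and the rule for named genes were fixed. Of the entries, 436 matched a gene. All but 1 of the 15 mitochondrial entries failed to match, so that list is close to void. The rule named ALKBH5, USP22 and RNF40, then up to 10 genes per direction with a peak in all 3 libraries of one condition and none of the other, ordered by their lowest within-list score percentile. It also named the 5 genes called in all 6 libraries with the highest such percentile, and up to 4 members of each list with the largest difference in libraries called, ties by symbol. Regions followed the same order.

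Library measures were compared with a two-sided exact permutation test of the difference of means, which cannot go below 0.1 with 3 against 3. Counts of regions or genes called in all libraries of one condition and none of the other were compared with the other 9 splits of the 6 libraries, in particular the 4 splits that part every same-numbered pair, the real one included. The agreement of direction between pairs was tested with Fisher's exact test on regions that differed in both pairs. Gene lists were tested with Fisher's exact test of members in more against fewer knockdown libraries, against all other genes, with Benjamini-Hochberg adjustment over the 20 lists and a threshold of 0.05. Intervals are 95% intervals and those of shares follow Wilson. After the counts were seen, gained and lost calls were also shuffled 10000 times among the regions that differed within each pair, with a fixed seed, with or without 5 classes of gene density or region length. For gene density this took the place of an earlier exact binomial test of the counts outside the densest class against equal shares, which left out the imbalance within pairs. The region counts and the agreement were tested on simulated lists built on the 21675 regions with the observed discordance between same-numbered libraries. With 200 changed regions per run, 15.9% were recovered as called in all knockdown and no control libraries when the odds of a call changed 16-fold, and 5.5% at 4-fold.

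The replicate numbers pair the libraries, because the protocol in the labels ties each number to an RNA type and antibody. The deviations of same-numbered libraries from their group means correlated across regions (0.24, 0.31 and 0.29 for replicates 1, 2 and 3). An exact sign-flip test of the 3 paired differences, with a smallest p of 0.25, was the paired alternative. The other alternatives were the best-scored 50% of each list, lists of equal size, each library or number left out, peaks extended by 100 bp, standard chromosomes only, overlapping peaks merged, genes with at least 2 peaks, and peaks of exactly 1 gene. After seeing the data, 3 further settings were added: coverage of at least 50% of a region, equal list size within each pair, and equal covered length within each pair.

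The share of peaks per transcript feature and the sequence motif at peaks were planned and not run, because neither an annotation nor a sequence of hg19 was used here. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures used matplotlib 3.10.9.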

Results

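N6-methyladenosine (m6A) was mapped on the RNA of 143B cells, an established human osteosarcoma line, after siRNA against ALKBH5, an enzyme that removes the methyl group from m6A, or after scrambled siRNA. The assay was MeRIP-seq, in which fragmented RNA is pulled down with an antibody against m6A and sequenced. Cells were harvested at 48 h. The 12 samples formed 4 groups of 3, an m6A immunoprecipitate and an input for each siRNA. The 6 immunoprecipitates each had 1 deposited peak list, analysed here, and the 6 inputs were not analysed here. Per the protocol in the labels, the replicate number also marked the method. Replicates 1 and 3 started from polyadenylated RNA with different antibodies, and replicate 2 started from total RNA with a commercial kit and a further antibody. The antibody field of the labels names the antibody of replicate 1 for all 6 libraries, so the antibodies of replicates 2 and 3 rest on the protocol text. Nothing in the labels says whether the numbers were separate cultures, and p-values between libraries measure only the spread between these samples. The series was made to find transcripts that ALKBH5 acts on.

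The peak lists held no read counts, so the depth behind each list is unknown. The knockdown libraries listed 17563, 5917 and 18360 peaks in replicates 1, 2 and 3, and the control libraries listed 15139, 5677 and 18724. All 6 lists together held 81380 peaks. Peaks that overlapped on the same strand were joined into 21675 regions, and the lists named 10536 genes. A region or gene is "called" in a library when that library's list has a peak there. A missing call does not show that the methyl mark was absent, since a peak can be missed at low RNA level or depth.

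ALKBH5, the siRNA target, had no peak in any of the 3 knockdown libraries and had peaks in 2 of the 3 control libraries. In control replicate 1 the peak covered 210 nt at chromosome 17, 18087673 to 18087882 (hg19, plus strand). In control replicate 3 it lay at 18111626 to 18111775 and covered 150 nt, so the controls shared no ALKBH5 site. The count of 0 of 3 against 2 of 3 libraries cannot reach significance in a design of this size, and peak calls are not RNA levels, so the efficiency of the knockdown was not measured here. USP22 and RNF40, an enzyme that takes ubiquitin off histones and a ligase that puts it on histone H2B, are known from what is published on this study as the targets it followed, so they are not independent evidence here. USP22 (gene number 23326 in the lists) was called in all 6 libraries, in 1 region at chromosome 17, 20905691 to 20906289 on the minus strand. Its peak covered 451, 181 and 481 nt in knockdown replicates 1, 2 and 3, and 331, 91 and 599 nt in the matching controls, longer in 2 of the 3 pairs. RNF40 (gene number 9810) had 6, 3 and 2 peaks in the knockdown libraries and 3, 0 and 3 in the controls, over 5 regions between 30779561 and 30787508 on the plus strand of chromosome 16. The RNF40 region at 30785292 to 30786101 was called in 3 knockdown libraries and 1 control library. The neighbouring RNF40 region at 30786190 to 30787508 was called in 3 knockdown and 2 control libraries. Whether these positions are coding or untranslated was not determined, since no annotation of the lists' genome build was used here.

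**Figure D1:**
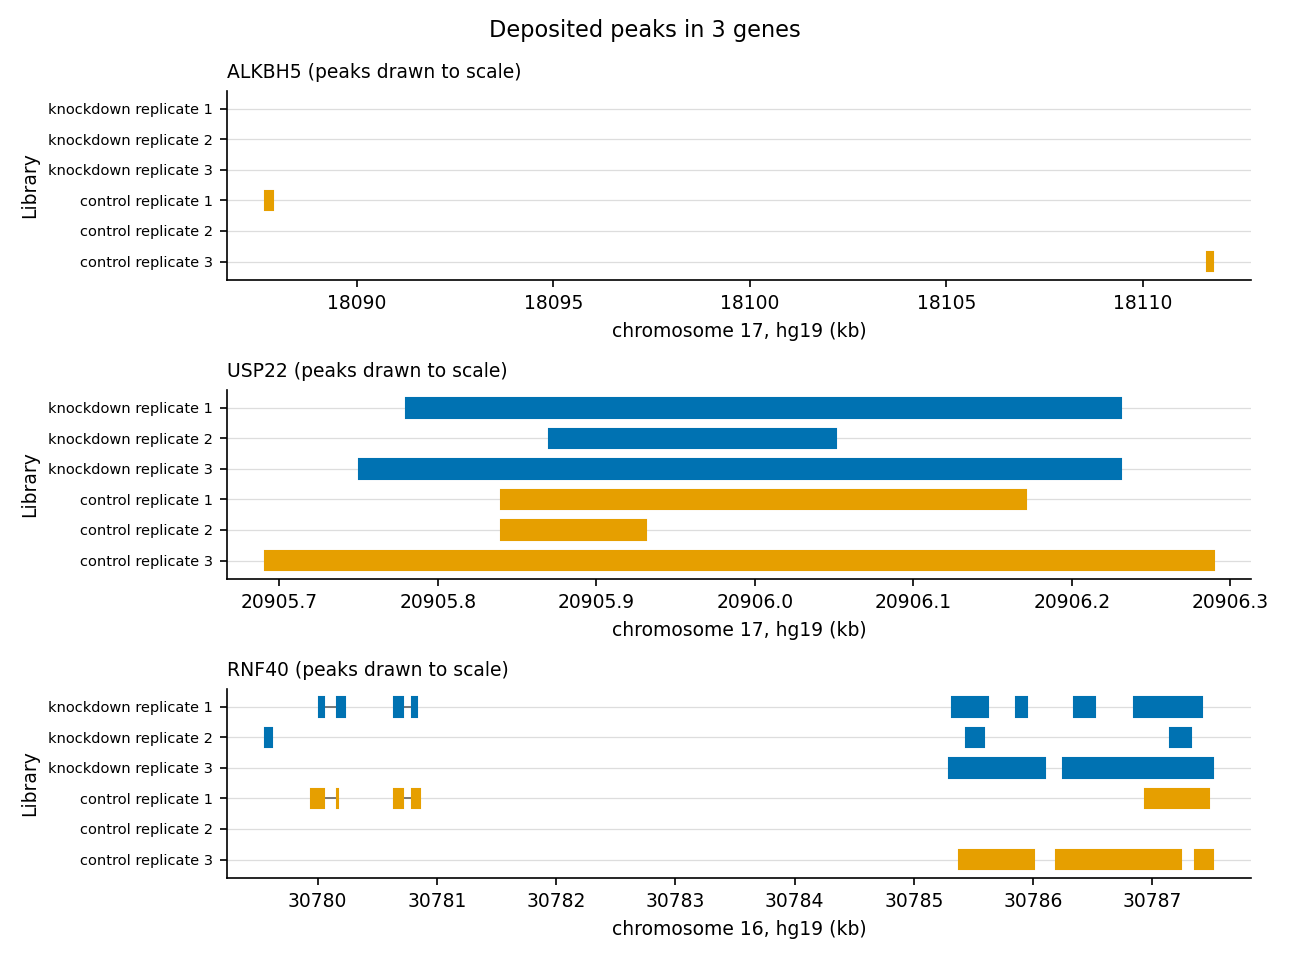
Deposited peaks in ALKBH5, USP22 and RNF40. The horizontal axis is the hg19 position in kb, each row is a library, boxes are exon blocks of peaks (blue, knockdown; orange, control) and thin lines join blocks of 1 spliced peak. ALKBH5 has peaks in 2 control libraries only, USP22 has a peak in all 6, and RNF40 lacks peaks in control replicate 2.

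The first comparison asked whether loss of the demethylase raised the number or extent of m6A peaks. Genes with a peak numbered 8267, 3373 and 9125 in knockdown replicates 1, 2 and 3 and 7010, 3305 and 9288 in the controls. The knockdown libraries held 13947 ± 6965 peaks (SD, n = 3) and the control libraries 13180 ± 6741 (SD, n = 3), a difference of 766.7 that lay far inside the spread between libraries (two-sided exact permutation test, p = 0.9, where 3 against 3 cannot go below 0.1). Within the same-numbered pairs the knockdown list held 2424 more peaks in replicate 1, 240 more in replicate 2 and a difference of -364 in replicate 3. Genes with a peak averaged 6922 ± 3103 (SD, n = 3) in the knockdown and 6534 ± 3020 (SD, n = 3) in the control, and did not separate the groups (exact permutation test, p = 0.9). The sign of the difference in peak number turned without knockdown replicate 1 (-1042), without knockdown replicate 3 (-1440) or without control replicate 2 (-2985). For genes with a peak it turned without the same libraries (-285.3, -714.3 and -1227). Without both libraries of replicate 1 the differences were -62 peaks and -47.5 genes. With covered length made equal within pairs, they were -3340 peaks and -1077 genes.

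The exon length covered by peaks was larger in the knockdown list of every pair. Peaks covered 5746, 1084 and 7855 kb in knockdown replicates 1, 2 and 3 and 3661, 961.2 and 7854 kb in the controls. The ratios within pairs were 1.57, 1.13 and 1.00, so nearly all of the difference came from replicate 1. The mean difference was 736.5 kb (exact permutation test, p = 0.7, n = 3 per group). The exact paired sign-flip test gave p = 0.25, the smallest value that 3 pairs allow. Median peak length was 269 nt against 209 nt in replicate 1, and was equal within the pair in replicates 2 and 3, at 151 nt and 331 nt. The covered length was lower in the knockdown without knockdown replicate 3 (-743.5 kb) or without control replicate 2 (-862.3 kb).

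**Figure D2:**
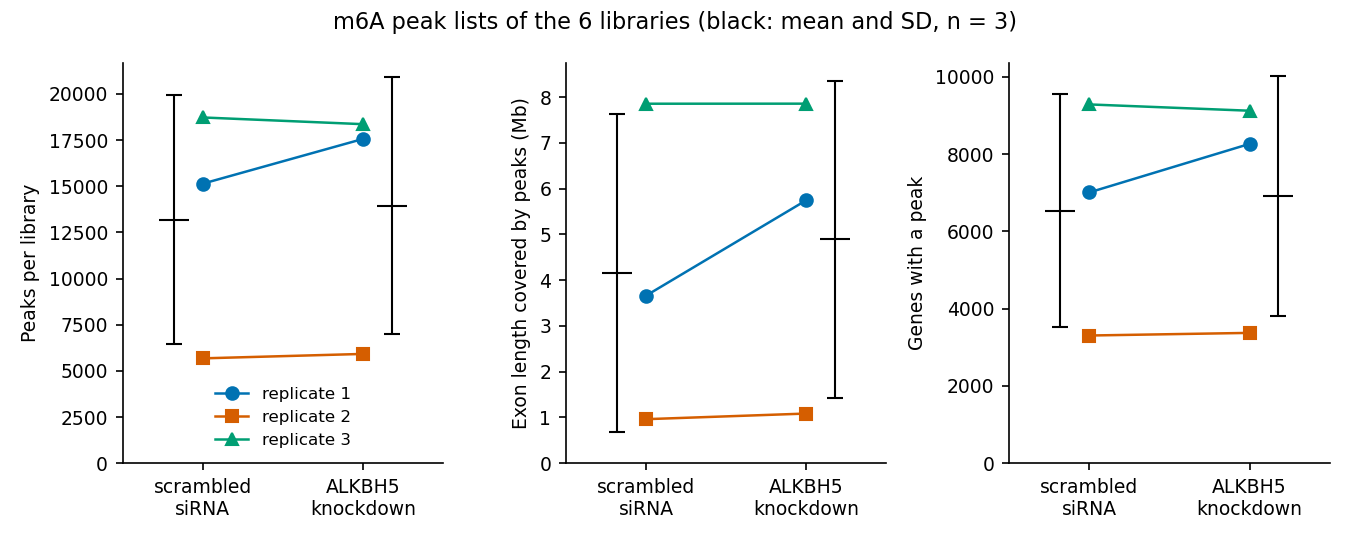
Peaks, covered exon length (Mb) and genes with a peak for each library, control at left and knockdown at right of each panel, with lines joining libraries of the same replicate number and black bars for the mean and SD of 3 libraries. Replicate 2 lies far below replicates 1 and 3 in both conditions, and the knockdown library of replicate 1 exceeds its control in all 3 measures.

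A core of transcripts carried peaks in every library. There were 2452 genes called in all 6 libraries, 23.3% of the genes with any peak, and 2759 regions, 12.7% of all regions. The 5 genes with the best-ranked peaks across all lists were DIDO1, SLC35E2B, SLC38A10, ARFGAP1, a GTPase-activating protein of the Golgi, and TRIM56, a RING-type ubiquitin ligase. DIDO1 carried between 7 and 10 peaks per library. The peaks of DIDO1 covered 4503, 2404 and 5489 nt in knockdown replicates 1, 2 and 3 and 2823, 1595 and 5759 nt in the controls.

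On average, peak sets resembled each other by replicate number more than by siRNA. Knockdown replicate 1 was an exception. Its Jaccard index (defined next) was 0.636 with knockdown replicate 3 and 0.600 with control replicate 3, against 0.588 with its own control. The Jaccard index, the regions shared by a pair of libraries over the regions called in either, averaged 0.616 ± 0.090 (SD, 3 pairs) for knockdown and control of the same number. It averaged 0.375 ± 0.157 (SD, 6 pairs) for libraries of the same siRNA and different number, and 0.367 ± 0.148 (SD, 6 pairs) for libraries that shared neither. The pairing by number gave the highest mean of the 6 ways to pair the libraries (exact permutation test, p = 0.167, the smallest possible). The same-number mean exceeded the same-siRNA mean by 0.241, and this gap was 0.0761 with all lists at equal size and 0.0866 without replicate 2. Regions of the shorter replicate 2 lists were mostly contained in the others. Of 4248 regions in knockdown replicate 2, 97.6% (95% Wilson interval 97.1 to 98.0%) were also called in a library of replicate 1 or 3, and of 4120 regions in control replicate 2, 97.8% (97.3 to 98.2%).

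**Figure D3:**
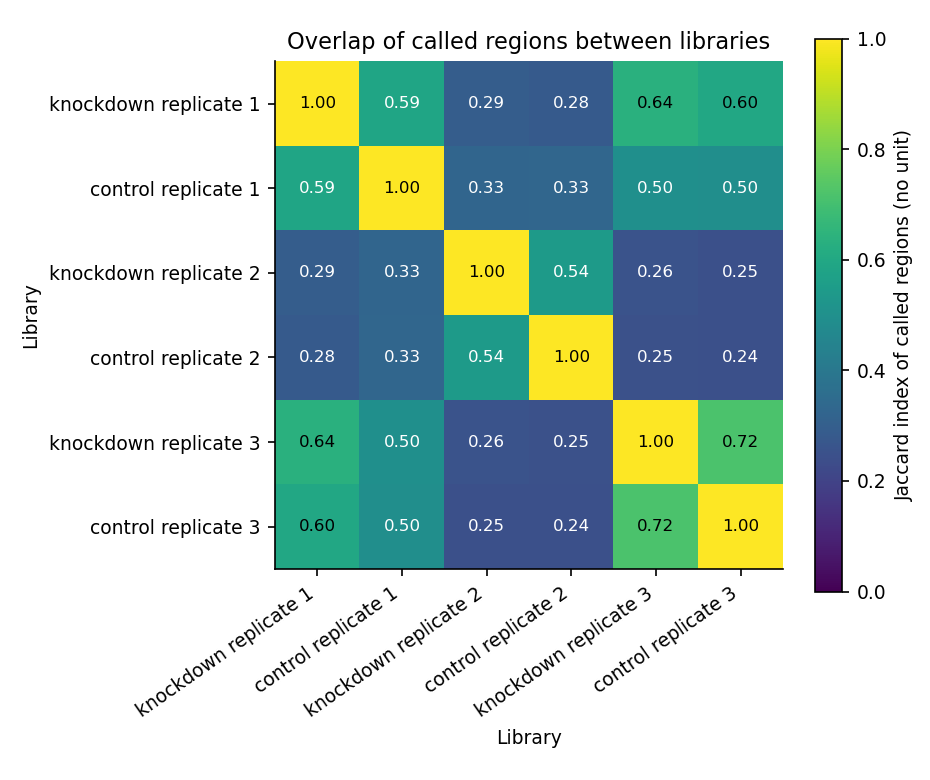
Jaccard index of called regions for every pair of the 6 libraries, with libraries on both axes ordered by replicate number and colour running from 0 to 1. Same-numbered knockdown and control libraries reach 0.59, 0.54 and 0.72, while pairs that join a replicate 2 library to a replicate 1 or 3 library lie between 0.24 and 0.33. Pairs that join a replicate 1 to a replicate 3 library lie between 0.50 and 0.64, within the range of the same-numbered pairs or just below it.

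A further comparison asked which sites were called in every knockdown library and no control library, or the reverse. There were 28 such regions for the knockdown and 2 for the control. The 28 included regions in GRK2, a kinase of G protein-coupled receptors, in KSR2, a scaffold of Ras signalling, in ABL1, a tyrosine kinase, in BRPF1, a subunit of histone acetyltransferase complexes, and in EXOC7, a subunit of the exocyst. The region in GRK2 lay at chromosome 11, 67051751 to 67052615 (plus strand, 301 nt of exon). That in KSR2 lay at chromosome 12, 117904645 to 117904945 on the minus strand. The region in ABL1 lay at chromosome 9, 133759497 to 133759886 on the plus strand. Other regions of the 28 lay in NPAS3, APC2 and SHB. Those in CHD3, CBX6, TAPBP, SPG7, CDK10 and WNK4 ranked lower and are named outside the order of the rule. In SPG7, CDK10 and WNK4 the lowest within-list percentiles were 0.71, 0.47 and 0.017, among the weakest calls of a list. The 2 regions of the control lay in HDAC9, a histone deacetylase (chromosome 7, 18705885 to 18706125), and PJA2, a ubiquitin ligase (chromosome 5, 108713944 to 108714212). Of the 28 regions, 7 lay in genes with no peak in any control library and 21 in genes with a peak elsewhere in at least 1 control library, of which 9 had such peaks in all 3. The 28 had a median exon length of 285.5 nt, against 329 nt over all regions and 360.0 nt over the 2983 regions called in exactly 3 libraries. In the library where each ranked lowest, their median within-list percentile was 12.4 (19.3 for the 2983 regions), on a scale where 100 is the best score.

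No single region can pass a test with 3 libraries against 3, so the counts were set against other splits of the libraries. Of the 4 splits that part every same-numbered pair, the real split gave 30 regions over both directions and the other splits gave 12, 5 and 2. These 4 splits are too few for a test, since 1 of them must come first. In simulated lists with no change and the observed number of discordant calls, 10.2 regions on average were called only in the knockdown and 11.2 only in the control, but those lists left out that calls in the real pair of replicate 1 were mostly gained (72.7%). Gained and lost calls were then shuffled among the regions that differed within each pair, which keeps the gained share over all such regions of a pair. This gave 8.63 regions on average called only in the knockdown and 3.42 only in the control (9.14 and 2.95 when shuffled also within classes of region length). As many as 28 arose in none of the 10000 shuffles (one-sided permutation test, p = 0.0001, the smallest they can give), and 2 or fewer for the control were not unusual (permutation test, p = 0.32). The shuffles ran across regions, which are not independent replicates. They also broke the link in direction between pairs that the odds ratios below measure, so the shuffles and those odds ratios are not separate evidence. Only the 49 regions that differed in every pair could enter the count, and the gained share among regions that differed in several pairs was not kept. Of the 417 regions that differed in replicates 1 and 2, 239 and 135 were gained in replicate 1 and 18 and 25 lost, a larger gained share. The shuffled counts may therefore be too low and the p too small. The counts changed with the way the lists were shortened. With the longer list of each pair reduced by score to the number of peaks of the shorter, they were 18 and 2, and with all 6 lists at equal size they were 66 and 24, with none of the 28 among the 66. With the larger list of each pair reduced to the covered length of the smaller, which left knockdown replicate 1 with 6694 peaks against 15139 in its control, 1 region was called only in the knockdown and 9 only in the control. That setting shortened only knockdown lists, and its list of knockdown replicate 1 held peaks in 4 of the 28, so most of the fall was fixed by the setting. Leaving out knockdown replicate 1, 2 or 3 gave 38 and 11, 503 and 2, or 44 and 16 regions, and leaving out control replicate 1, 2 or 3 gave 41 and 19, 33 and 187, or 222 and 10.

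**Figure D4:**
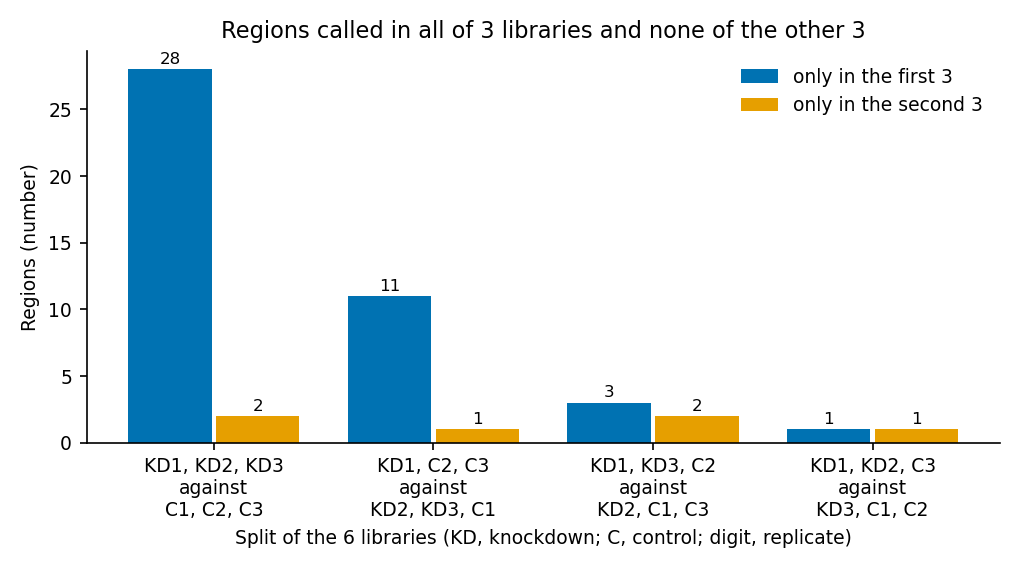
Number of regions called in all of 3 libraries and none of the other 3, for the 4 splits of the 6 libraries that part every same-numbered pair, with blue bars for the part that holds knockdown replicate 1 and orange bars for the other part. The real split, at left, has 28 and 2 regions, and the next has 11 and 1.

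At the level of genes, 12 had a peak in every knockdown library and in no control library, and 3 the reverse. The 10 best ranked of the 12, by lowest within-list percentile, were KSR2, SEPTIN10, PLCD4, MBD6, COMTD1, GSDMD, EIF2B5, PNPLA6, MRPL4 and TMEM229B. For EIF2B5, PNPLA6, MRPL4 and TMEM229B that percentile was only 5.82, 4.62, 2.84 and 1.05. Peaks of MBD6, EIF2B5 and MRPL4 lay in 2 regions each and those of GSDMD and PNPLA6 in 3. None of those regions was called in all 3 knockdown libraries and no control library, so no shared site was found for these genes. GSDMD is the pore-forming protein of pyroptosis, EIF2B5 a subunit of the exchange factor for eIF2, and MRPL4 a protein of the mitochondrial ribosome. GET4, named after its values were seen, was also among the 12. The 3 genes of the control were PJA2, HSPA4, a heat shock protein of the HSP70 family, and CAST, which encodes the calpain inhibitor calpastatin. The KSR2 peak covered 151, 151 and 301 nt in knockdown replicates 1, 2 and 3. The CAST peaks covered 91, 91 and 61 nt in control replicates 1, 2 and 3, but lay in 3 separate regions, so the controls shared no CAST site. HSPA4 peaks lay in 2 regions, and neither was called in all 3 controls and no knockdown library. The other splits that part every pair gave 2, 1 and 0 genes over both directions, against 15 for the real split, again too few splits for a test. At equal covered length within pairs, which shortened only knockdown lists, 0 genes were called only in the knockdown and 9 only in the control, and at equal size of all lists the counts were 51 and 18. Leaving out knockdown replicate 1, 2 or 3 gave 16 and 11, 176 and 3, or 19 and 12 genes, and leaving out control replicate 1, 2 or 3 gave 21 and 6, 14 and 85, or 132 and 8.

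Regions that differed in 2 pairs tended to differ the same way in both, although the pairs came from different protocols and shared no library. Most regions that differed in 1 pair differed in no other. Within replicates 1, 2 and 3, 6337, 2476 and 5307 regions differed. Of these, 417 differed in both replicates 1 and 2, 1064 in both 1 and 3, and 111 in both 2 and 3. Within replicate 1, 4605 regions were gained, that is called in the knockdown and not in the control, and 1732 were lost. In replicate 2 there were 1302 gained and 1174 lost, and in replicate 3 there were 2446 gained and 2861 lost. Among the 111 regions that differed in both replicate 2 and replicate 3, 52 were gained in both, 39 were lost in both and 20 went opposite ways (odds ratio 20.3, 95% interval 7.69 to 53.5, Fisher's exact test, p = 1.2e-11). For replicates 1 and 3 the odds ratio was 4.33 (3.20 to 5.85, Fisher's exact test, p = 3.0e-23), with 511 regions gained in both and 189 lost in both. For replicates 1 and 2 it was 2.46 (1.29 to 4.67, Fisher's exact test, p = 0.0075), and it was 1.92 with p = 0.062 when only the best-scored 50% of each list were kept. Calls of genes gave odds ratios of 13.3, 6.71 and 2.43 for the same pairs of replicates. Fisher's tests were two-sided and ran across regions or genes, which are not independent replicates, and all 6 had a Benjamini-Hochberg adjusted p of 0.027 or below. Simulated lists with no change gave odds ratios of 0.96, 0.99 and 0.95. Each simulated library was drawn independently, so values near 1 were fixed by construction. They check the calculation only and are no measure of chance in the real lists.

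Gene lists fixed in advance were compared by the number of members called in more or in fewer knockdown than control libraries. Over all genes, 2746 were called in more knockdown libraries, 1801 in fewer and 5989 in as many, so that 60.4% of the genes that differed were in more. That share was 50.6% with all lists at equal size, 54.9% with equal size within pairs, 48.3% without replicate 1 and 21.9% with equal covered length within pairs. By Fisher's exact test against all other genes, 0 of the 20 lists passed after Benjamini-Hochberg adjustment and 1 had an unadjusted p under 0.05. The exact permutation test of members per library passed 0 lists, which was fixed in advance, since 3 against 3 cannot go below 0.1. With that shift of all genes at equal covered length, 9 lists turned in direction and 0 passed.

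The list with the smallest p was that of replication-dependent histones, whose transcripts end in a stem-loop in place of a poly(A) tail. Of its 8 members with a peak, 7 were called in more knockdown libraries and 0 in fewer (Fisher's exact test, p = 0.047, adjusted p = 0.62). H4C8 was called in 2 knockdown libraries and no control library, H2BC21 in 3 and 2, and H2AC11 and H3C10 in 2 and 1. Of 20 genes of osteoblasts and bone matrix, 9 were called in more and 2 in fewer (Fisher's exact test, p = 0.22, adjusted p = 0.81), among them COL1A1 and CTNNB1 (2 knockdown and 1 control library), COL5A1 (3 and 2) and BGLAP, which encodes osteocalcin (1 and 0). At equal covered length within pairs where 21.9% of all genes that differed were in more, the bone list had 1 in more and 6 in fewer and the histones had 3 and 1. Of 16 osteosarcoma drivers, 0 were in more and 3 in fewer (Fisher's exact test, p = 0.062, adjusted p = 0.62). These were MDM2, the ligase of p53, the receptor MET and the helicase BLM, each called in 2 knockdown and 3 control libraries. All 3 lacked a peak only in knockdown replicate 2, so their direction rests on that library.

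The list of histone H2A and H2B ubiquitination, which holds USP22 and RNF40, had 34 members with a peak, 6 in more and 8 in fewer knockdown libraries (Fisher's exact test, p = 0.27, adjusted p = 0.81). BAP1 and CUL4B were in 2 knockdown and 1 control library, and KDM2B and BARD1 in 2 and 3. Because the study chose USP22 and RNF40 on these samples, the list is not independent evidence of direction. Of the 10 m6A writers, 9 had a peak, with 1 in more (CBLL1, 3 and 2 libraries) and 0 in fewer (Fisher's exact test, adjusted p = 1). With 1 member that differed, this test could not show a direction. WTAP, VIRMA, RBM15, RBM15B, ZC3H13 and METTL16 were called in all 6 libraries, so calls cannot show whether their methylation changed. The catalytic METTL3 and its partner METTL14 were each called in 2 knockdown and 2 control libraries. Among 13 erasers and readers of m6A, 3 were in more and 3 in fewer (Fisher's exact test, adjusted p = 1). FTO, the other known m6A demethylase, was called in 3 knockdown and 2 control libraries. The list of ALKBH5 targets from other studies had 4 in more and 1 in fewer of 14 (Fisher's exact test, adjusted p = 1). PER1, SOX2 and FOXO1 were called in 3 knockdown and 2 control libraries, and GLI1 in 0 and 1.

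Cell cycle genes had 4 members in more and 0 in fewer of 16 with a peak (Fisher's exact test, p = 0.16, adjusted p = 0.81), namely AURKA, CDK2, E2F1 and BUB1, with 0 and 8 at equal covered length within pairs (21.9% of all genes in more). In the full lists each of these 4 genes differed only within replicate 1, whose knockdown list held 2424 more peaks than its control. Immediate early genes had 3 in more and 6 in fewer of 25 (Fisher's exact test, p = 0.17, adjusted p = 0.81). EGR2 was called in 2 control libraries and no knockdown library. Genes of DNA damage and repair had 2 in more and 3 in fewer of 16 (Fisher's exact test, adjusted p = 0.88). Interferon and innate sensing genes had 4 in more and 3 in fewer of 17 (Fisher's exact test, adjusted p = 1). ISG15 and STAT2 were called in 2 knockdown and 0 control libraries, and IFIT1 and IFI44 in 1 and 2. Apoptosis genes had 4 in more and 1 in fewer of 20 (Fisher's exact test, adjusted p = 1), among them PMAIP1 (3 knockdown and 2 control libraries). Polycomb and histone methylation genes had 3 in more and 1 in fewer of 27, and extracellular matrix and adhesion genes had 4 in more and 2 in fewer of 21 (Fisher's exact test, adjusted p = 1 for both). MMP2 was called in 2 knockdown and 0 control libraries, and LAMB1 in 0 and 2.

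Cytosolic ribosomal protein genes had peaks in 3 of 30 members, all called in more knockdown libraries (Fisher's exact test, adjusted p = 0.81). Nuclear and small noncoding RNAs had 3 members with a peak, KCNQ1OT1, MALAT1 and NEAT1, each called in 2 knockdown and 2 control libraries, with none in replicate 2. The mitochondrial genome list had no member with a peak, and only 1 of its 15 entries could be matched to a gene. The lists of markers of other cell types held 15 immune, 14 epithelial and 10 endothelial genes. Among them CLDN3, ENG and ERG were called in every library. There were 2 immune, 4 epithelial and 3 endothelial markers with a peak, and of these 1, 1 and 0 were called in more knockdown libraries and 0, 0 and 1 in fewer (Fisher's exact test, adjusted p = 1, 1 and 0.88).

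**Figure D5:**
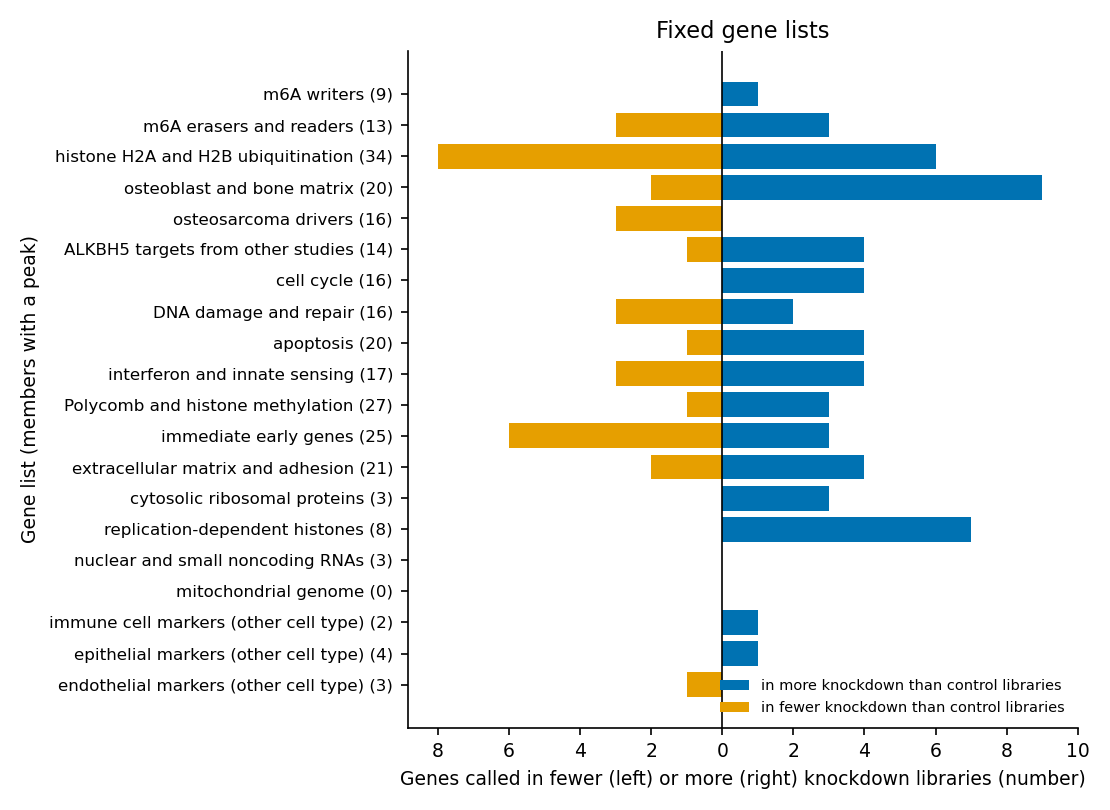
Members of each fixed gene list called in more (blue, right) or fewer (orange, left) knockdown than control libraries, on a horizontal axis of gene number, with the members that had any peak in parentheses. The longest bars are 9 genes of osteoblasts and bone matrix at right and 8 genes of histone ubiquitination at left, the former had 1 against 6 at equal covered length within pairs (21.9% of all genes in more), and no list passed the adjusted threshold.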

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

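The comparison with other splits was planned, the other tests in this part were chosen after the result was seen, and for the one that set covered lengths equal within pairs the deciding value was fixed before its own outcome was seen.

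The pairs of libraries moved in opposite directions in list size. In replicate 3 the knockdown list held fewer peaks than its control (a difference of -364), while it held 2424 more in replicate 1 and 240 more in replicate 2. The same held for genes with a peak (-163 in replicate 3, against 1257 and 68) and for called regions (-415, against 2873 and 128). Each protocol had 1 pair, so the difference between protocols was not tested.

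More regions were called only in the knockdown libraries than only in the controls, 28 against 2. Gene-dense surroundings alone are argued against, although 12 of the 28 regions lay in the densest of 5 classes of local gene density (genes named in the lists within 500 kb), which held 18.5% of all regions: outside that class the counts were 16 and 2, and with directions shuffled within pair and density class, 9.90 regions on average were called only in the knockdown (one-sided permutation test, p = 0.0001, the smallest possible). A surplus of gained calls spread evenly over the regions that differed within each pair is argued against as the whole cause. Shuffling directions within pairs gave 8.63 regions on average (same permutation test, p = 0.0001). These shuffles ran across regions, which are not independent replicates. With or without density classes, they did not keep the larger gained share of replicate 1 among regions that also differed in replicate 2. A surplus that is larger in such regions remains open. At equal peak number within pairs 18 of the 28 were left, against 2. That setting could not decide, since the knockdown lists still covered 668.8 kb more on average. A wider cover of the knockdown lists remains open. At equal covered length 1 region was called only in the knockdown and 9 only in the control. That outcome met the condition fixed in advance for wider cover as the cause. It was set aside on a ground outside that condition: the setting by itself left 4 of the 28 in knockdown replicate 1, so the outcome was taken to decide nothing. A change of the whole gene, in RNA level or in methylation, may also contribute, since other regions of the same genes were gained 37 times and lost 10 times over the pairs (odds ratio 2.80 against all other regions, stratified by pair, 95% interval 1.38 to 5.68), and without the inputs RNA level and methylation could not be separated. The 10 splits of the 6 libraries are too few for a share under 0.05: 7 gave as many regions as the real 30. The highest other, 2141, set knockdown replicates 1 and 3 and control replicate 3, the longest lists, apart from the shorter ones. It parted 1 same-numbered pair, that of replicate 1, so it did not follow the protocols alone. For genes 7 of the 10 splits gave as many as the real 15, and the highest other, from the same split, was 1047.

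Regions that differed in 2 pairs of different protocols tended to gain or lose calls the same way. Most regions that differed in 1 pair differed in no other. Ease of detection is argued against as the whole cause, because odds ratios stratified by the calls of the remaining pair and by region length were 2.71 or above (lowest: 95% interval 1.34 to 5.46). Gene-dense surroundings are argued against in the same way, with a lowest stratified odds ratio of 2.51 (1.27 to 4.94). These intervals also ran across regions, which are not independent replicates, and may be too narrow. A change of the whole gene remains open and is consistent with neighbouring regions: where exactly 2 regions of a gene differed within a pair, they differed the same way in 64.7% of genes in replicate 1 (95% interval 61.4 to 67.9%), 67.6% in replicate 2 and 65.8% in replicate 3, against 60.3, 50.1 and 50.3% by chance. The knockdown itself, through methylation or through RNA level, is among the open explanations, as is an RNA source shared between the numbers, which was not tested.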

How the results depend on the processing

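The settings with equal size or covered length within pairs and with coverage of a region were chosen after seeing the data. Pairing by replicate number (the replicate block) left the mean differences of 766.7 peaks, 736.5 kb and 387.3 genes as they were, with exact sign-flip p = 0.75, 0.25 and 0.75, and it changed no call. The number of gene lists past the adjusted threshold was 0 under every setting run. Standard chromosomes, merging of overlapping peaks and extension by 100 bp changed no direction or call of the comparisons they were run on. The planned overlap of 50% of the shorter of peak and region was not run, because a peak always lies wholly in its region, and coverage of 50% of the region took its place. The counts of regions and genes seen in all libraries of one condition and none of the other moved under most settings that shorten or leave out lists. The direction agreement kept an odds ratio above 1 in every setting run, from 1.92 to 3.35 for replicates 1 and 2, 3.59 to 9.71 for replicates 1 and 3 and 10.0 to 25.4 for replicates 2 and 3. Depth, which sets list length, could not be varied without reads.

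With the best-scored 50% of each list, 9 regions and 5 genes were called only in the control (2 and 3 in the full lists), the odds ratio between replicates 1 and 2 was 1.92 and 26 regions were called only in the knockdown, which by construction cannot include any of the 28, since each of these ranked at percentile 35.5 or lower in at least 1 list. With all lists at equal size, 66 regions and 51 genes were called only in the knockdown and 24 and 18 only in the control. With equal size within pairs 18 regions were called only in the knockdown. With equal covered length within pairs, regions numbered 1 in the knockdown and 9 in the control, and genes 0 and 9, and the mean differences turned to -3340 peaks and -1077 genes, in a setting that by construction shortened only knockdown lists. With at least 50% of a region covered, regions numbered 14 and 1. Shorter lists hold fewer calls by construction, and beyond that the cause was not tested.

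Leaving out libraries gave ranges of -2985 to 4782 for the difference in peaks, -862.3 to 2642 kb for covered length, -20.3 to 70.3 nt for median peak length and -1227 to 2162 for genes. Regions ranged from 33 to 511 for the knockdown and from 2 to 189 for the control, and genes from 14 to 179 and from 3 to 85. The lowest and highest values of the library differences came from leaving out a single library of replicate 2, or of replicate 3 for peak length, which unbalances the protocols.

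For the gene lists, the number of members in more minus in fewer knockdown libraries turned in sign under some settings. With the best-scored 50% it was 1 for histone ubiquitination, -7 for interferon and innate sensing and 6 for immediate early genes. With equal list sizes it was -2 for apoptosis, -2 for interferon and innate sensing, -1 for extracellular matrix and -1 for epithelial markers. With 2 or more peaks per gene it was 3 for histone ubiquitination and 1 for immediate early genes. With libraries left out it ranged from -2 to 3 for m6A writers, -14 to 16 for histone H2A and H2B ubiquitination, -8 to 5 for osteosarcoma drivers, -4 to 10 for ALKBH5 targets from other studies, -2 to 11 for cell cycle, -7 to 6 for DNA damage and repair, -8 to 13 for apoptosis, -7 to 9 for interferon and innate sensing, -3 to 7 for Polycomb, -8 to 4 for immediate early genes, -5 to 9 for extracellular matrix and -2 to 3 for epithelial markers. At equal covered length within pairs it was -2 for m6A writers, -5 for osteoblast and bone matrix, -5 for ALKBH5 targets from other studies, -8 for cell cycle, -8 for apoptosis, -6 for interferon and innate sensing, -3 for Polycomb, -3 for extracellular matrix and -3 for epithelial markers, in a setting where 21.9% of all genes that differed were in more, and 0 lists passed (Fisher's exact test, smallest adjusted p = 0.70). In share of libraries called, knockdown minus control, KDM2B turned to 0.333 and CD44 to -0.333 with the best-scored 50%, BAP1 to -0.333 with equal sizes and IFIT1 to 0.333 with peaks of exactly 1 gene. Of the other values of named genes, 1244 stayed within 1 library in 3 of those reported and 54 moved further without turning. Beyond the shorter lists, the cause of these turns was not tested.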

Other observations

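The tests of gene families in this part were chosen after the data were seen. For the zinc finger genes, the tests against other splits and within classes of density and length were chosen after the pattern but before their own outcomes were seen, and the test within chromosome 19 after. Grouping all genes by the letters that open their symbols gave 62 families with at least 8 genes that differed between conditions. Of these, 5 passed after Benjamini-Hochberg adjustment of Fisher's exact test against all other genes, which are not independent replicates. Genes with ZNF symbols, mostly zinc finger transcription factors, were called in more knockdown libraries in 39 cases and in fewer in 75 (Fisher's exact test, adjusted p = 9.5e-07), while 60.4% of all genes that differed were in more. ZNF207, ZNF221, ZNF335 and ZNF608 were each called in 2 control libraries and no knockdown library. Genes with SLC symbols, mostly solute carriers, showed the opposite balance, 72 in more and 20 in fewer (Fisher's exact test, adjusted p = 0.0051). SLC12A4, SLC2A3 and SLC5A6 were called in 3 knockdown libraries and 1 control library. At equal covered length within pairs the SLC counts turned to 24 and 61, still above the share of the other genes (odds ratio 1.41, Fisher's exact test, p = 0.18).

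Genes with CEP symbols, mostly centrosomal proteins, had 2 in more and 13 in fewer (Fisher's exact test, adjusted p = 0.0050), and METTL genes, a family of methyltransferases, had 1 and 8 (adjusted p = 0.043). METTL6 and METTL25 were called in 2 control libraries and no knockdown library. With all lists at equal size the counts were 3 and 8 for CEP (Fisher's exact test, p = 0.14) and 1 and 5 for METTL (p = 0.12), and with the best-scored 50% METTL had 4 and 4. The 13 PCDHA genes, protocadherins, were all in fewer, but their peaks made up 1 region, so they count as a single observation, and other settings were not run for them. The genes with the most peaks over all lists were AHNAK2 with 96, DST with 77 and ZNF469 with 76. PCLO had 19, 0 and 14 peaks in knockdown replicates 1, 2 and 3 and 11, 0 and 19 in the controls, so its peaks came from the poly(A) libraries alone.

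The lower calling of ZNF genes relative to other genes was weighed further: their regions were gained 35 times and lost 65 times in replicate 2 and 56 and 174 times in replicate 3, but gained 139 and lost 73 times in replicate 1, where they were lower only relative to other genes (odds ratio 0.707). Position on chromosome 19, where many of these genes cluster, is argued against: on that chromosome the odds of being gained, ZNF against other genes and stratified by pair, were 0.329 (95% interval 0.236 to 0.458), though in replicate 1 alone they were 0.842 (Fisher's exact test, p = 0.51). Gene density and region length are argued against as well, since stratifying by both and by pair gave an odds ratio of 0.415 (0.343 to 0.502), against 0.493 stratified by pair alone. The intervals of these odds ratios ran across regions, counted once for each pair in which they differed and often several to a gene. Such regions are not independent replicates, so the intervals may be too narrow. The 10 splits are too few for a share under 0.05: 2 gave as strong an imbalance, with a -log10 p of 7.81 for the real split and 8.05 for the highest other, which set knockdown replicate 1 with control replicates 1 and 3 and parted 1 pair, while the other splits that part every pair gave 4.92, 0.878 and 0. The odds ratio against other genes stayed below 1 in the 8 other settings run, from 0.198 with equal covered length within pairs to 0.508 with the best-scored 50%, with 0.415 without replicate 2 and 0.332 in the full lists, and base composition, reads shared between paralogs and RNA level remain open, since no genome sequence or input was analysed here.

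The densest of the 5 classes of local gene density had the highest share of gained regions in replicates 2 and 3, without a steady rise over the other classes. In replicate 2 gained regions made up 69.9% of those that differed in the densest class and 49.6% in the sparsest, and in replicate 3 they made up 57.0 and 42.5%. The lowest shares, 38.5 and 40.1%, were those of the class next to the sparsest. In replicate 1 the shares of the densest and sparsest classes were 73.8 and 72.9%, and that of the class next to the densest was also 73.8%. The difference between protocols was not tested, and neither was a trend or an explanation.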
